A study of Arabidopsis thaliana with 6 samples.

How the data were processed

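The series holds 6 Affymetrix ATH1 arrays hybridised with biotin-labelled total RNA of Arabidopsis thaliana Col-0. Per the labels' protocols, seeds were kept for 24 h at 4 °C, and plants were grown on soil for 3 weeks at 23 °C, 50% relative humidity and a 16 h photoperiod and used before flowering. The groups were taken from the agent in the labels, control or saliva, with 3 arrays each, and the replicate numbers from the labels.

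The deposited values are probe set signals, an intensity on a linear scale, 1 per probe set and array. The submitters' processing notes name MAS5, GCOS and limma without saying what each was used for, and their versions are not given in the sources used here. The deposited signals of each array had the same mean of 100.01 once the lowest and highest 2% of probe sets were left out, so the scaling was kept. No detection calls were used here. The table had 0 columns of another sample.

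The 64 Affymetrix control probe sets were left out, signals were put on the scale log2(signal + 16), and the 40% of the remaining 22746 probe sets with the lowest mean log2 value over all 6 arrays were left out. This left 13647 with a mean log2 value of at least 5.04, which corresponds to a signal of 16.8 and can lie below the plain mean of the signals. Differences on this scale understate the change of dim probe sets. Saliva was compared with control in R 4.3.3 with limma 3.58.1 (lmFit, and eBayes with a mean-variance trend), with the group as the factor and a two-sided Benjamini-Hochberg adjusted p under 0.05 as the threshold. Values written as ± without further words are standard errors from this fit.

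Gene names came from the platform's annotation table, updated through gene identifiers in a RefSeq gene table of assembly TAIR10.1, in which 99.4% of the identifiers were found. This gave 13513 probe sets with 1 gene and 503 with several genes, from which no name was taken, and 8730 are unnamed here, not without a gene. Of those tested, 7367 have 1 gene, 280 have several and 6000 are unnamed here. No coordinates are given.

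Gene lists were fixed before the data were examined: 21 lists with 361 entries, matched by locus, for jasmonate, salicylate, ethylene, early pattern-triggered defence, camalexin and tryptophan, indole and aliphatic glucosinolates, touch and wounding, oxidative stress, phenylpropanoids, abscisic acid with cold and drought, auxin, heat shock, senescence and starvation, photosynthesis, the clock, protein folding, and markers of flower, root, phloem and guard cells. Of the entries, 1 was left out because its symbol and locus disagree, 51 were named on the array and 40 were tested. The lists thus cover a small part of what they were meant to cover. Lists with at least 3 tested members, 4 in all, were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Families by annotated name needed at least 5. A gene with several probe sets is represented by the one with the highest mean over all 6 arrays. The named genes are the 12 largest rises and 12 largest falls among probe sets with 1 gene, an adjusted p under 0.05 and no overlap of the groups, filled up to 12 by the smallest unadjusted p, up to 4 members of each list by the smallest unadjusted p, and PR1, PDF1.2, VSP2, LOX2, PAD3, CYP81F2 and FRK1 where measured. The 4 unnamed probe sets past the threshold are given as well.

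A further 5 lists were written after the leading genes were seen, for sugar starvation and dark-induced genes, class III glutaredoxins, plastid ribosomal proteins, cytosolic ribosomal proteins and tetrapyrrole synthesis. The last of them was written after the tests of the other 4 had been seen. Their adjusted p is over these 5 lists. The lists were written from memory by locus, and their members were not checked against a source. In the order given, 13 of 33, 13 of 21, 8 of 37, 54 of 102 and 8 of 23 members were tested. The others were under the filter or had no probe set named here. For the weighing of single patterns, both tests were run alike on all of them and adjusted over the lists of each setting, a choice made after the first tests had been seen, because those had differed between patterns. The calls over a list alone without single arrays, the splits without the members seen first, and the tests of the glutaredoxins outside the cluster and without the 3 seen first, adjusted over these 2, were added after the values had been seen.

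The fit was tested on simulated data with 13647 probe sets, in 10 simulations of saliva against control with 200 changed probe sets each. It recovered 43.6% of changes of 0.5 on the log2 scale, 98.9% of changes of 1 and 100% of changes of 1.5 and 2, and 5.45% of its calls were false. The simulated noise was independent between probe sets, with the spread of the moderated fit. Most planted changes were of 1 or more in size, which eases the adjusted threshold. These shares therefore need not hold for the real arrays, where AT1G54020 at 1.26 did not pass. The alternatives tried were an offset of 1 or 64, no filter or one at 60%, quantile normalization, median centring, the replicate number as a block, no mean-variance trend, array weights, no moderation, a threshold of 0.1, a change of at least 1 on the log2 scale, and each array left out in turn.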

Results

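Transcript levels were measured in wild-type Arabidopsis thaliana (accession Col-0) with and without saliva of Myzus persicae, the green peach aphid, which feeds on phloem sap and injects saliva as it feeds. Plants were 3 weeks old and had not flowered. There were 6 ATH1 arrays, each giving a signal for 22810 probe sets, with 3 control and 3 saliva arrays. The labels used here do not state the tissue, how saliva was applied, the time after treatment or what the control plants received. Nothing in the labels says whether the replicates of a group came from separate plants or separate experiments, so the p-values measure the spread between these arrays, which may be technical. The trimmed mean signal was 100.01 on every array, and the median signal lay between 32.4 and 33.4. The precision is limited by the number of arrays.

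The arrays were similar to each other, with Pearson correlations between 0.975 and 0.988 over the 13647 probe sets tested. The first principal component held 31.9% of the variance. The control arrays lay at -7.07, -13.0 and -8.30 on it and the saliva arrays at 0.369, 5.31 and 22.7, so that the groups did not overlap. Saliva replicate 3 stood farthest from the rest. It was also the array with the lowest mean correlation to its own group, at 0.980. Saliva replicate 1 correlated no better with its own group, at a mean of 0.9832, than with the controls, at 0.9837.

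The main comparison asked which transcripts differed between saliva and control plants. EXO (AT4G08950), a brassinosteroid-responsive gene that promotes cell expansion, rose by 1.04 ± 0.15 (SE) on the log2(signal + 16) scale, a 2.06-fold difference. AT1G50040 rose by 0.99 ± 0.15 and AT1G62510, which encodes a protein of the lipid-transfer and seed-storage superfamily, by 0.85 ± 0.13. AT1G06830, which encodes a class III (CC-type) glutaredoxin, fell by 0.76 ± 0.12. The adjusted p was 0.0496 for each of these 4 genes, and in each the 3 saliva arrays lay all above or all below the 3 control arrays. Without saliva replicate 1, EXO (adjusted p = 0.0128) and AT1G06830 (adjusted p = 0.0396) passed, and none of the 4 passed without any of the other 5 arrays. With each array left out in turn the values were at least 0.89 for EXO, 0.89 to 1.11 for AT1G50040, 0.73 to 0.93 for AT1G62510 and -0.85 to -0.70 for AT1G06830. The control mean of AT1G50040 was 5.03, just below the lowest mean log2 value that the filter kept. It passed the filter through its saliva mean of 6.01, and whether its control signal exceeded background was not tested. Over all alternatives AT1G50040 ran from 0.48 to 1.51.

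The change with the smallest adjusted p belonged to probe set 253161_at, which is unnamed here and rose by 1.58 ± 0.13, from a mean of 7.47 ± 0.12 (SD, n = 3) to 9.04 ± 0.24 (SD, n = 3), with a limma adjusted p of 0.000295. Probe set 246004_at, also unnamed here, fell by 0.93 ± 0.12, from a mean signal of 2303 to 1212, with an adjusted p of 0.0265. Probe sets 252415_at and 246987_at, unnamed here as well, rose by 0.90 ± 0.14 and 0.67 ± 0.11, each with an adjusted p of 0.0496. Without single arrays 253161_at passed each time, at 1.45 to 1.69, and 246004_at passed without saliva replicate 1 alone, at -1.07 in a range of -1.07 to -0.86. The other 2 did not pass with any single array left out, at 0.77 to 0.97 for 252415_at and 0.61 to 0.71 for 246987_at. Over all alternatives 252415_at ran from 0.49 to 1.24.

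**Figure D1:**
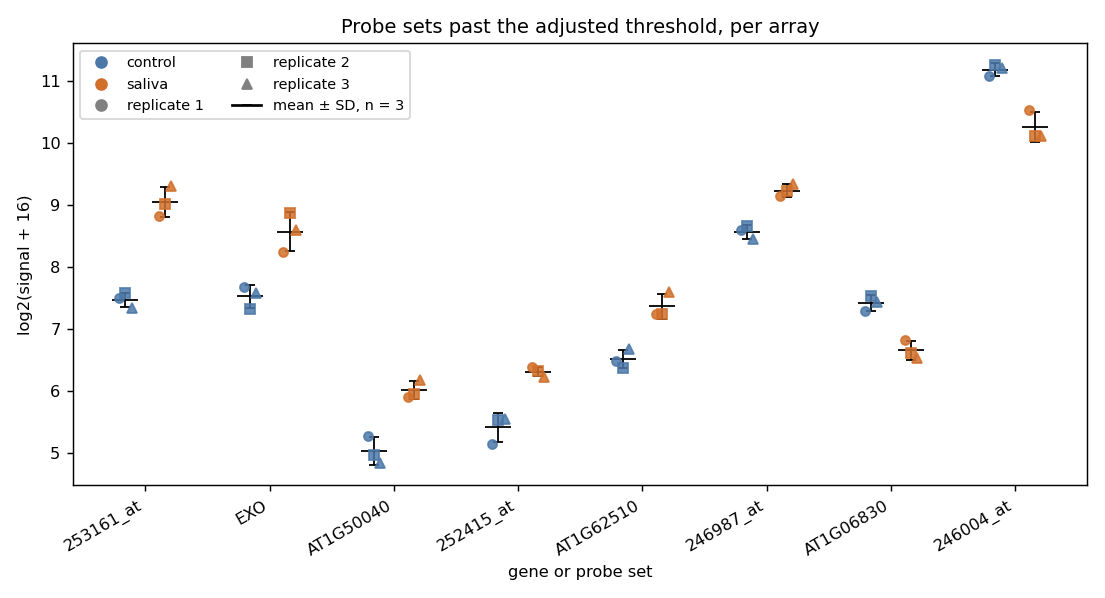
The vertical axis gives log2(signal + 16) and the horizontal axis the 8 genes or probe sets past the adjusted threshold; points are single arrays, coloured by group and shaped by replicate number, and black bars are the mean ± SD of 3 arrays. The saliva arrays of 253161_at centre on 9.04 against 7.47 in the controls, and those of 246004_at on 10.2 against 11.2.

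In all, 8 of the 13647 probe sets tested passed an adjusted p of 0.05 in limma, 6 higher and 2 lower with saliva, and 4 of them have 1 gene in the table used for names. At an unadjusted p under 0.05 there were 1394 probe sets, 736 higher and 658 lower, against 682 by chance. The 3 saliva values lay all above or all below the 3 control values in 2119 probe sets, 15.5% of those tested, where chance gives 10%. Of these, 1065 were higher and 1054 lower. The count of 8 rests on each array: it was 1, 2 and 1 without control replicate 1, 2 and 3, and 14, 1 and 2 without saliva replicate 1, 2 and 3. Other settings gave from 1 to 53, with 1 higher and 0 lower under quantile normalization and 1 higher and 1 lower with the arrays centred on their medians.

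Other leading genes did not pass the threshold, and their values are given without a call. Among the higher ones, AT1G54020 differed by 1.26 ± 0.24 (adjusted p = 0.0673), AT4G27450, which encodes a protein of the aluminium-induced family, by 0.89 ± 0.16 (adjusted p = 0.0578), and AT1G80130 by 0.87 ± 0.15 (adjusted p = 0.0578). AT5G57655, which encodes xylose isomerase, differed by 0.74 ± 0.13 (adjusted p = 0.0578). AT2G47440, AT4G29950 and AT1G68440 differed by 0.57, 0.59 and 0.62, and ALDH7B4 (AT1G54100), an aldehyde dehydrogenase gene, by 0.50 (adjusted p = 0.110).

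Among the lower ones, the glutaredoxin genes AT2G47880 and AT4G15680 differed by -0.68 ± 0.12 and -0.59 ± 0.12, with adjusted p of 0.0578 and 0.0702. AT1G29070, which encodes a protein of the plastid ribosome, differed by -0.48 ± 0.098 (adjusted p = 0.0894). AT5G51890, a peroxidase gene, differed by -0.80 ± 0.17 (adjusted p = 0.110), and AT3G11930, which encodes a universal stress protein, by -0.53 ± 0.11 (adjusted p = 0.116). AT1G78170, AT5G01015, AT3G08740, AT1G14345, AT5G08050 and AT3G62820 differed by -0.75, -0.64, -0.54, -0.55, -0.55 and -0.51.

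The next question was whether genes of the fixed lists moved together. The 4 measured auxin response genes were all higher with saliva, by a mean of 0.46 on the log2 scale (camera adjusted p = 0.00151). The call was lost with adjusted p = 0.14 with an estimated correlation. WES1 (AT4G27260), the GH3.5 enzyme that joins auxin to amino acids, differed by 0.87 ± 0.16, and GH3.3 (AT2G23170), of the same enzyme family, by 0.58 ± 0.21. IAA29 differed by 0.28 ± 0.17 and HAT2 by 0.12 ± 0.14. The control means of WES1 and GH3.3 were 4.95 and 5.01, below the lowest mean log2 value that the filter kept. They passed the filter through their saliva means of 5.83 and 5.59, and whether their control signals exceeded background was not tested. IAA29 and HAT2 were brighter, with control means of 5.68 and 7.18, and differed less. The mean of the list thus rests largely on genes that were dim in the controls. None of the 4 passed over all genes tested, and 2, WES1 and GH3.3, rose when adjusted over the list alone. GH3.3 did not without control replicate 1 (0.31), saliva replicate 1 (0.62) or saliva replicate 3 (0.47), and IAA29 passed over the list alone without control replicate 3 (0.47). Without single arrays the values ran from 0.31 to 0.79 for GH3.3, 0.10 to 0.47 for IAA29 and 0.038 to 0.26 for HAT2. Over all alternatives WES1 ran from 0.41 to 1.38 and GH3.3 from 0.25 to 1.05.

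The 7 measured photosynthesis genes were all lower with saliva, by a mean of -0.15 (camera adjusted p = 0.0124). The call was lost with adjusted p = 0.244 with an estimated correlation. PRK and SBPASE, enzymes of the Calvin cycle, differed by -0.23 ± 0.095 and -0.21 ± 0.088. LHCB4.1, a light-harvesting protein gene, differed by -0.21 ± 0.090, and ATPC1, of the plastid ATP synthase, by -0.17 ± 0.098. 0 of the 7 passed over all genes and 0 when adjusted over the list alone, while 3 had an unadjusted p under 0.05. With quantile normalization PRK was -0.14, SBPASE -0.12, LHCB4.1 -0.11 and ATPC1 -0.058, and ATPC1 was -0.080 without saliva replicate 1. With quantile normalization the mean was -0.050 with 2 of 7 members higher (adjusted p = 0.366), and without saliva replicate 1 it was -0.11 with 1 of 7 higher (adjusted p = 0.117), in a range of adjusted p from 0.00181 to 0.366 over the alternatives.

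Of the 4 measured genes of the abscisic acid, cold and drought response, 3 were higher, with a mean of 0.18 (camera adjusted p = 0.0855, and adjusted p = 0.244 with an estimated correlation). COR47, a dehydrin gene, differed by 0.47 ± 0.13 and rose when adjusted over the list alone, but not over all genes (adjusted p = 0.184). LTI30, another dehydrin gene, differed by 0.28 ± 0.11, COR15A by 0.098 ± 0.14 (0.17 with quantile normalization) and COR15B by -0.13 ± 0.15. Over the list alone COR47 did not pass without saliva replicate 2 (0.32), and LTI30 passed without control replicate 3 (0.33) and saliva replicate 3 (0.32). The list passed with quantile normalization (mean 0.21, adjusted p = 0.0443) and without control replicate 2 (mean 0.28, adjusted p = 0.0124), and its adjusted p ran up to 0.342 over the alternatives.

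Of the 8 measured genes of early pattern-triggered defence, 6 were higher and 2 lower, with a mean of 0.080 (camera adjusted p = 0.318). 0 of the 8 passed over all genes or when adjusted over the list alone, and 0 had an unadjusted p under 0.05. WRKY53, a transcription factor gene of immunity and senescence, differed by 0.33 ± 0.20. CML41, PUB23 and the receptor-associated kinase gene BIK1 differed by 0.24 ± 0.16, 0.17 ± 0.13 and 0.15 ± 0.11. Without single arrays the mean of the list ran from 0.031 to 0.15, WRKY53 from 0.18 to 0.57, CML41 from 0.088 to 0.33, PUB23 from 0.12 to 0.26 and BIK1 from 0.093 to 0.23.

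**Figure D2:**
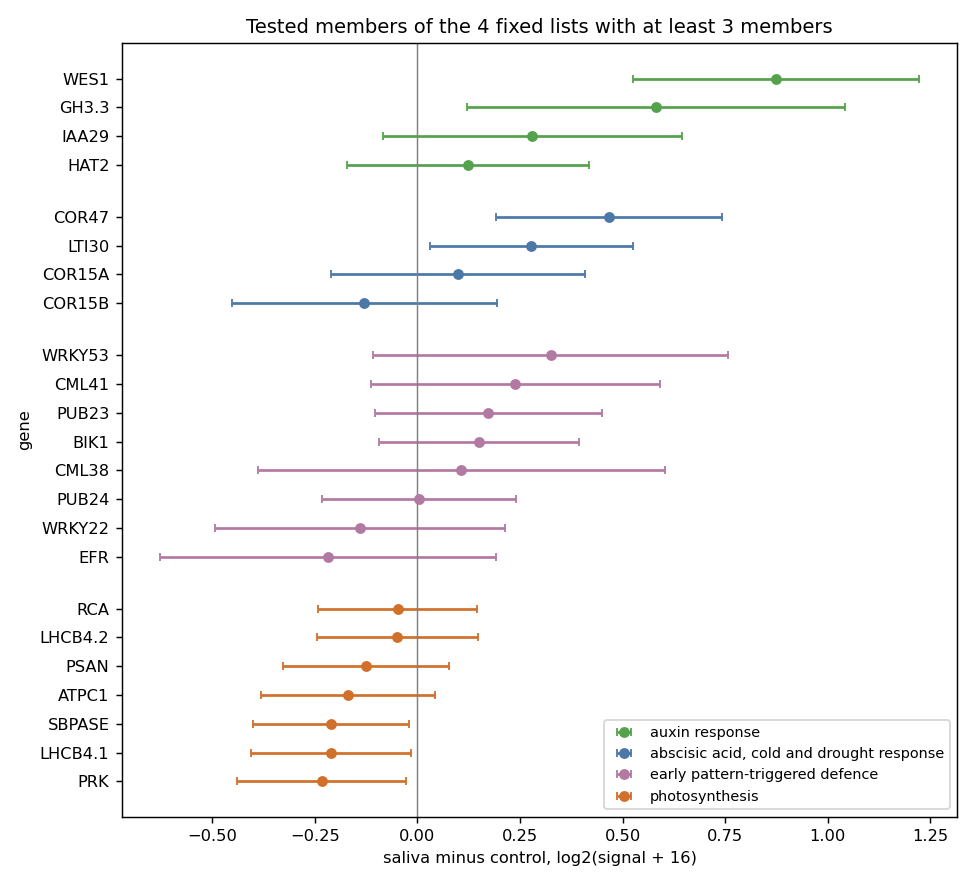
The horizontal axis gives the difference of saliva minus control in log2(signal + 16) and the vertical axis the tested genes of the 4 lists with at least 3 tested members, coloured by list; points are estimates and bars 95% confidence intervals from limma with 3 arrays per group. The auxin response genes lie between 0.12 and 0.87 and the photosynthesis genes between -0.23 and -0.048; with quantile normalization 2 of the 7 photosynthesis genes lie above 0.

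Of the other 17 lists, 12 had 1 or 2 tested genes each, too few for a list test, and 5 had 0 (heat shock, protein folding, and markers of flower, root and phloem). 0 of their named and tested genes passed over all genes tested. Unnamed probe sets, some of them past the threshold, may belong to further members of these lists. WRKY6 (AT1G62300), a transcription factor gene of senescence, was the tested gene of the senescence and starvation list and differed by 0.52 ± 0.13 (adjusted p = 0.173 over all genes). It passed when adjusted over the list alone, which for a list of 1 tested gene is no adjustment. AT2G31790, a glucosyltransferase gene of aliphatic glucosinolate synthesis, differed by -0.29 ± 0.11 and fell when adjusted over the list alone (adjusted p = 0.359 over all genes). BCAT4, of the same list, differed by -0.026 ± 0.11. UGT74B1, of indole glucosinolate synthesis, differed by -0.23 ± 0.12, and AT2G04400, of tryptophan synthesis, by 0.20 ± 0.12. Over the list alone AT2G31790 did not pass without control replicate 1 (-0.31), 2 (-0.27) or 3 (-0.29) or saliva replicate 1 (-0.20). UGT74B1 and AT2G04400, each the 1 tested gene of its list, had an unadjusted p under 0.05 without saliva replicate 1 (-0.32) and control replicate 3 (-0.30), and without saliva replicate 2 (0.28). Without single arrays AT2G04400 ran from 0.12 to 0.28.

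PDF1.2, a defensin gene that responds to jasmonate and ethylene, differed by 0.21 ± 0.11 (adjusted p = 0.559). The jasmonate methyltransferase gene JMT differed by -0.059 ± 0.21, and the thionin gene THI2.1 was under the filter on dim probe sets, with a mean log2 value of 4.69 in the controls and 5.33 with saliva. In the fit without that filter it differed by 0.64 ± 0.19 (adjusted p = 0.470). In the ethylene list EIN3 differed by 0.17 ± 0.10. In the salicylate list SAG101 differed by 0.15 ± 0.12 and GRX480 by 0.11 ± 0.20. STZ, of the touch and wounding list, differed by -0.25 ± 0.28 (it had an unadjusted p under 0.05 without control replicate 1, at -0.61, and was 0.081 without control replicate 2), and AT2G21640, of the oxidative stress list, by -0.050 ± 0.14. The flavonoid glycosyltransferase genes UGT78D2 and UGT78D1 differed by 0.11 ± 0.13 and -0.056 ± 0.16, and UGT78D2 ran from 0.040 to 0.21 without single arrays. The clock gene GI differed by -0.049 ± 0.11. PR1, VSP2, LOX2, PAD3, CYP81F2 and FRK1 have no probe set named here and were not analysed by name, though they may be among the unnamed probe sets tested.

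Among the markers of other tissues and cell types, the guard cell gene FMA had a mean log2 value of 5.97 in both groups (adjusted p = 1.00, SE 0.12). The root genes PYK10, EXPA7 and EXPA18 were under the filter on dim probe sets, with mean signals of 6.07, 4.49 and 2.54 in the controls and 4.43, 7.39 and 2.70 with saliva. No marker of flower tissue or phloem and no gene of protein folding in the endoplasmic reticulum was named here. The named heat shock gene, ATHSP22.0, was under the filter, at a mean signal of 12.1 in the controls and 9.51 with saliva.

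Families formed by words in gene names gave 9 groups with at least 5 tested members. The ribosomal protein family was lower, in 14 of 16 members and by a mean of -0.22 (camera adjusted p = 0.000235). The call was lost with adjusted p = 0.578 with an estimated correlation. The family was formed from names alone and holds none of the cytosolic ribosomal protein genes of the list written later. The 54 tested members of that list had a mean of -0.089, so the family does not stand for ribosomal protein genes at large. Which genome encodes the family's 16 members, that of the nucleus or of an organelle, was not examined here. The other 8 families did not pass: WRKY, glutathione transferases, cytochromes P450, expansins, xyloglucan enzymes, peroxidases, UDP-glycosyltransferases and histones, with camera adjusted p between 0.531 and 0.840.

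As a sign of RNA quality, the log2 ratio of the 3-prime over the 5-prime probe set of Affymetrix control genes was compared by a two-sided exact permutation test, whose smallest possible p with 3 arrays against 3 is 0.1. The ratio of GAPDH was 0.51 ± 0.091 (SD, n = 3) in the controls and 0.48 ± 0.15 with saliva (exact p = 0.8). That of Actin was 3.55 ± 0.31 and 3.59 ± 0.31 (SD, n = 3; exact p = 0.9), and that of Ubq was 1.36 ± 0.047 and 1.23 ± 0.37 (SD, n = 3; exact p = 0.7). The adjusted p was 0.9 for each. On single arrays the Actin ratio ran from 3.23 to 3.93, so a large excess of 3-prime signal for Actin was shared by both groups. These tests compare the groups and do not judge the quality that the arrays share. Of the 64 control probe sets, 0 passed an adjusted p of 0.05 in limma and 0 had an unadjusted p under 0.05.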

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

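The tests of the gene families with an estimated correlation and with fry, and those of the list members under the filter, were chosen only after the result was seen. The count of 8 changed probe sets moved by more than 1.5 times under each of its 18 alternatives. It was 2 with an offset of 1, 2 with an offset of 64, 1 with no filter on dim probe sets, 2 with the lowest 60% left out, 1 without a mean-variance trend, 53 with array weights and 1 without moderation, and that call was none of the 8. It was 50 at an adjusted p under 0.1, and 2 with a change of at least 1 on the log2 scale. With quantile normalization it was 1 (1 higher, 0 lower) and with median centring 2 (1 higher, 1 lower), against 6 higher and 2 lower. Without single arrays it ran from 1 to 14. The cause was not tested. Whether the replicate numbers pair the arrays is unclear. The deviations of same-numbered arrays correlated at -0.059, 0.116 and 0.152 for replicates 1, 2 and 3, and those of differently numbered arrays at -0.168 to 0.0889. Partial pairing, which the main fit does not use, stays open. With the replicate block the count was 29, the 8 among them, and not every array correlated best with its own number (saliva replicate 1 with control replicate 2, at 0.0889).

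Probe set 253161_at kept its call in 15 of 16 alternatives, with adjusted p between 9.79e-05 and 0.344, and 246004_at in 7 of 16. The other 6 kept theirs in 2 or 3. Of 59 named genes and probe sets, 49 kept their direction in every alternative, among them the 24 leading genes, whose groups do not overlap, so that leaving out 1 array cannot reverse them, and 17 that had not passed did so in at least 1. The other 10 reversed in at least 1, and none was past the threshold where it reversed. BCAT4 was 0.054 with quantile normalization, and GRX480 was -0.043, AT2G21640 0.024 and FMA 0.0093 with array weights. Without single arrays the values ran from -0.22 to 0.17 for JMT, -0.13 to 0.35 for GRX480, -0.094 to 0.090 for BCAT4, -0.61 to 0.081 for STZ, -0.11 to 0.049 for AT2G21640, -0.20 to 0.12 for UGT78D1, -0.24 to 0.059 for COR15B, -0.074 to 0.26 for COR15A, -0.092 to 0.034 for GI and -0.046 to 0.060 for FMA.

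Auxin response was past the threshold in 14 of 16 alternatives, with means of 0.23 to 0.74, 0.35 to 0.57 without single arrays and adjusted p of 3.63e-05 to 0.14. It was lost with an estimated correlation (mean 0.46, adjusted p = 0.14) and with fry (0.46, adjusted p = 0.0717), and had too few members with the lowest 60% left out. Photosynthesis was past it in 13 of 17, and was lost with an estimated correlation and fry (mean -0.15, adjusted p = 0.244 and 0.0717), quantile normalization (-0.050) and without saliva replicate 1. In both lists every alternative that passed used camera at the preset correlation of 0.01. The estimated correlation was 0.108 for auxin response and 0.300 for photosynthesis, so these counts do not test that setting. The means of photosynthesis ran from -0.19 to -0.11 without single arrays. The abscisic acid list passed with quantile normalization (0.21), and its means ran from 0.12 to 0.28 without single arrays. Early defence did not pass in any of 17 alternatives (adjusted p of 0.0649 to 0.708).

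The number of families past the threshold was 1, and 0 with an estimated correlation and 0 with fry. Component 1 held 28.7% with no filter, where 3005 of the 22746 probe sets had groups without overlap, against 2119 of the 13647 tested with it. The differences in 3-prime to 5-prime ratio ran through 0 without single arrays: -0.12 to 0.031 for GAPDH, -0.14 to 0.18 for Actin and -0.33 to 0.030 for Ubq. Signal over background was not tested, since no detection calls were used here, and the 11 fixed list members under the filter on dim probe sets were tested in limma in the fit without it, where 0 passed (adjusted p of at least 0.470) and 2, THI2.1 and UGT73B5, had an unadjusted p under 0.05.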

Other observations

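The lists of this part, the tests of the glutaredoxins, the comparison of both list tests and the splits of the arrays were chosen only after the leading genes were seen, and the members named here after their values were seen. Genes that sugar starvation and darkness induce were higher with saliva in 12 of 13 tested members, by a mean of 0.34 on the log2 scale (camera adjusted p = 8.15e-07, and adjusted p = 0.0356 with an estimated correlation). The list has 33 members, and over all genes 0 of the 13 tested passed in limma. Unnamed probe sets, some of them past the threshold, may belong to further members. Of the 13, 8 had an unadjusted p under 0.05 and 7 rose when adjusted over the list alone. That last count was 3, 3 and 4 without control replicate 1, 2 and 3, and 4, 5 and 3 without saliva replicate 1, 2 and 3. AKINBETA1 (AT5G21170), a subunit of the energy-sensing SnRK kinase, differed by 0.37 ± 0.12. AT4G33150, of lysine breakdown, differed by 0.70 ± 0.25 and by 0.35 without saliva replicate 3, and IVD (AT3G45300), of branched-chain amino acid breakdown, by 0.24 ± 0.11. AT1G23390 was the member in the other direction, at -0.16 ± 0.10, and ran from -0.22 to -0.096 without single arrays.

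All 8 tested genes of tetrapyrrole synthesis, the route to chlorophyll and haem, were lower with saliva, by a mean of -0.32 (camera adjusted p = 4.38e-07). The call was lost with adjusted p = 0.0705 with an estimated correlation, while fry, which does not compare the list with other genes, passed (adjusted p = 0.00929). 5 fell when adjusted over the list alone, against 3 without saliva replicate 2 or control replicate 3 and 8 without saliva replicate 1. HEME1, GSA1 and LIL3:1, which were seen before the list was written, differed by -0.46, -0.43 and -0.42, and PORB by -0.32 ± 0.10. The other 5 members had a mean of -0.25 (fry adjusted p = 0.0296, and adjusted p = 0.106 with an estimated correlation). Cytosolic ribosomal proteins were lower in 41 of 54 members by a mean of -0.089 (camera adjusted p = 0.000568). That call was lost with adjusted p = 0.357 with an estimated correlation, with fry (adjusted p = 0.319) and without control replicate 3 (mean -0.025, adjusted p = 0.298), and the mean was -0.14 without control replicate 1.

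The higher level of the starvation genes was weighed against 3 technical explanations. With quantile normalization the mean was 0.34 (adjusted p = 0.0411 with an estimated correlation), which argues against the scaling of the arrays. Without saliva replicate 3 it was 0.28, and the 11 members not seen beforehand had a mean of 0.26, where fry passed (adjusted p = 0.0389 and 0.0112) and camera with an estimated correlation did not once adjusted over the lists (adjusted p = 0.101 and 0.0633). Both means stayed positive, but the tests do not decide whether that array or the choice of the list is the whole source. Fry does not compare the list with other genes. The test without saliva replicate 3 includes the members seen beforehand, and the 11 others were listed after those had been seen. A response to saliva may account for the pattern, as a hypothesis found and tested on the same arrays, and differences between the groups in light at harvest, time of day or tissue, which the labels used here do not give, stay open.

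Class III glutaredoxins were lower in 10 of 13 members, by a mean of -0.28 (camera adjusted p = 3.28e-06), a call lost with adjusted p = 0.0726 with an estimated correlation, and 6 fell when adjusted over the list alone, with 5 to 7 without single arrays. The mean was -0.30 with quantile normalization and -0.22 without saliva replicate 3, and fry passed in each (adjusted p = 0.0213 and 0.0428), while camera with an estimated correlation did not (adjusted p = 0.0896 and 0.118). The mean did not shrink in size with quantile normalization, which argues against scaling as its whole source. Whether that array is the whole source stays undecided, since the fry calls include the 3 genes seen first for their falls on these arrays. Without those 3, fry did not pass on all 6 arrays (adjusted p = 0.121). The 9 members outside the tandem cluster on chromosome 4, 2 of them seen first, had a mean of -0.26 with 3 of 9 higher, where fry passed (adjusted p = 0.0296) and camera with an estimated correlation did not (adjusted p = 0.126). Cross-hybridization within the cluster and the choice of the list both stay open, since the 10 members other than the 3 seen first had a mean of -0.16 (adjusted p = 0.158 with an estimated correlation), and the 7 of these outside the cluster one of -0.13 with 3 of 7 higher (adjusted p = 0.198, and 0.139 by fry).

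Nucleus-encoded plastid ribosomal proteins were lower in 8 of 8 members, by a mean of -0.28 (camera adjusted p = 4.75e-06), a call lost with adjusted p = 0.0726 with an estimated correlation, and 4 fell when adjusted over the list alone, against 1 without control replicate 2, control replicate 3 or saliva replicate 3 and 8 without saliva replicate 1. The mean was -0.22 with quantile normalization and -0.25 without saliva replicate 3, where fry passed unadjusted and not when adjusted over the lists (adjusted p = 0.0509 and 0.0592). Camera with an estimated correlation did not pass in either (adjusted p = 0.144 and 0.147). Scaling and that array therefore stay open as part of the source, since the means moved toward 0. Without saliva replicate 3, fewer arrays also widen the error. Without single arrays the mean ran from -0.33 to -0.24. The 7 members without AT1G29070 had a mean of -0.25 (fry adjusted p = 0.0416, and adjusted p = 0.129 with an estimated correlation), and no biological explanation beyond saliva was tested.

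The 6 arrays can be parted into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 8 changed probe sets and the highest of the others 1, and at an unadjusted p under 0.05 it gave 1394 and the highest of the others 828. The mean of each of these 5 lists lay as far from 0 in 1 of the 10 splits, the real one: auxin response at 0.46 against at most 0.35 in the others, photosynthesis at 0.15 against 0.11, starvation genes at 0.34 against 0.22, glutaredoxins at 0.28 against 0.20 and plastid ribosomal proteins at 0.28 against 0.22. The last 3 lists hold genes seen in the real split, which favours it. Without those members the starvation genes lay at 0.26 against 0.16 and the plastid ribosomal proteins at 0.25 against 0.23, each in 1 of the 10 splits, and the glutaredoxins at 0.16 against 0.16, in 2 of the 10.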
